A study of Mus musculus with 28 samples.

How the data were processed

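Gene expression was measured on 28 Affymetrix mouse 430 2.0 arrays hybridised with total RNA of p63 knockout and wild-type Balb/c tissues. The tissues were bladder at embryonic days 15, 18 and 19 (E15, E18 and E19) and proximal stomach, distal stomach, small intestine and large intestine at E18. Each genotype in each tissue and stage had 2 arrays, which gives 14 groups. Per the labels' protocols, RNA was extracted with Trizol, labelled with biotin and amplified with a 3' IVT express kit. The p63 gene carries the symbol Trp63 in mouse. The allele, the dissection and the number of animals are not given in the sources used here. The labels do not say whether the replicates are separate animals, so the p-values measure the spread between samples.

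The deposited values are 1 number per probe set and array on the log2 scale, between about 3 and 15, with no value missing. Affymetrix Expression Console and Partek are named per the submitters' processing notes, without a version. Background correction, summarization and normalization are not given in the sources used here. The arrays do not share identical quantiles, and their medians lie between 7.48 and 7.86. The number of arrays limits the precision, and the arrays give no counts or depth.

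The values were used as deposited. Of 45101 probe sets, 64 control probe sets were left out, and 45037 remained. Of these, 34945 carry 1 gene symbol, 932 carry several and 9160 carry none. For 34754 probe sets the symbol equals that of a RefSeq annotation of mouse assembly GRCm38.p6 joined by gene identifier, and 204 have an identifier missing from it. That annotation served for names alone, so coordinates are not given. A probe set was kept when it lay above the array's own median on at least 2 of the 28 arrays, which left 28866. A gene was represented by the probe set with the highest mean over the 28 arrays among those with 1 symbol, which left 13613 genes.

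Models were fitted with limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), and figures and joins used Python 3.11.15. One model held all 28 arrays with a mean per group, 14 residual degrees of freedom, 6.19 prior degrees of freedom and a trend of the variance with the mean. Contrasts were knockout minus wild type in each of the 7 tissues and stages, their mean over the 3 bladder stages and over all 7, 4 differences of these contrasts between tissues or stages, and 4 contrasts among wild-type groups. P-values are two-sided and adjusted by the method of Benjamini and Hochberg over the genes of a contrast. A gene was called at an adjusted p under 0.05. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so calls rest on limma's spread pooled over genes and groups. A gene is termed separated when both knockout values lie above, or both below, the 2 wild-type values. Chance gives 33.3% of genes in 1 tissue.

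Gene lists were fixed before the data were examined, as were the contrasts, the filter, the threshold and the rule for naming genes. The 30 lists are basal stratified epithelium; squamous differentiation and cornified envelope; simple and columnar epithelium; urothelial differentiation; gastric glandular; intestinal epithelium; hindgut and colon; ciliated cells; enteroendocrine; smooth, skeletal and cardiac muscle; fibroblast and matrix; neurons and glia; immune cells; endothelium; erythroid cells; mesothelium; liver; pancreas; Wolffian duct, prostate and kidney; proliferation; p53 targets; the Hedgehog, Wnt and Notch pathways; regional patterning factors; immediate early and heat shock; hypoxia and glycolysis; and sex-linked genes. Some genes stand in more than 1 list, such as Krt19 and Fabp1. Lists were tested with limma's camera, which compares a list with the other genes, at a preset correlation between genes of 0.01 and again with a correlation estimated from the residuals. Adjustment ran over the 210 pairs of list and tissue. In addition, 6 signatures were formed from genes at least 4-fold higher in 1 wild-type E18 region than in each of the others, and were tested in the knockout contrasts of proximal stomach and bladder E18. The region under test was left out of the definition, and intestine means higher in both small and large intestine.

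The rule named Trp63 by each of its probe sets first. It then took, among genes called and separated, the 10 largest increases and decreases in bladder E18, proximal stomach and the bladder mean, and the 5 largest each way in the other contrasts. Genes without a full name and sex-linked genes were passed over. For each list spoken of, up to 4 members with the largest change among those past the test were added.

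The pipeline was tested on simulated data built from the same design, with 50 genes changed at each size. It recovered 22% of changes of 0.5 on the log2 scale, 82% of changes of 1 and 100% of changes of 2 and of 3 in 1 tissue. It called 12 of 13413 unchanged genes there. For a difference between tissues it recovered 131 of 200 changed genes with 4 false calls.

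The numbers 1 and 2 of the replicates were tested as pairs across tissues, from correlations across genes of the residuals. The 6 pairs of wild-type gut tissues gave correlations between 0.126 and 0.333, with a median of 0.266, and all 6 were above 0.1. The 72 other pairs of groups gave a median of 0.0152. Those of knockout gut tissues gave 0.0128 to 0.349, with a median of 0.113 and 3 of 6 above 0.1. The numbers therefore pair the wild-type gut arrays, and sex-linked genes split the knockout gut arrays by number too. With replicate number as a block, 5692 genes differed between wild-type proximal and distal stomach and 6085 between small and large intestine, against 5504 and 5917 without it.

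The alternatives tried were quantile normalization, median centring, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, limma without a trend and with robust priors, array weights, only the arrays of the groups compared, replicate number as a block, a minimum of 2-fold, an 8-fold threshold for signatures, an estimated correlation for lists, and leaving out each array in turn. Leaving out an array leaves 1 array in a group, whose spread is then assumed to be like that of the other groups. Alternatives added after the data were seen leave out the bladder E19 or E15 arrays, or fit covariates for the 3' minus 5' actin signal or for Xist and Eif2s3y. The closing section gives their effects. The probe sets with no symbol or several entered no comparison of genes and were tested apart.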

Results

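The 28 arrays from p63 knockout and wild-type mice form 14 groups of 2 arrays. Thus n = 2 behind each group mean, and ± marks the SD of the 2 values. Changes are knockout minus wild type on the log2 scale, SE is limma's standard error and p is limma's adjusted p. The 2 arrays of a group correlated across genes at 0.980 to 0.994, and the SD of their difference ranged from 0.236 in knockout bladder E19 to 0.411 in wild-type large intestine. The first principal component held 36.9% of the variance and the second 18.7%.

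Among the wild-type tissues Trp63 was highest in proximal stomach, followed by bladder, and low in the intestine. By the probe set with the highest mean its level was 13.24 ± 0.11 in wild-type and 13.72 ± 0.08 in knockout proximal stomach, a difference of 0.49 that missed the threshold (adjusted p = 0.415). The 3 other probe sets of Trp63 were higher in knockout proximal stomach by 0.91 (adjusted p = 0.0010), 1.12 (adjusted p = 2.1e-04) and 1.63 (adjusted p = 4.3e-04). In bladder E19 the first probe set fell by 2.44, from 11.97 ± 0.43 to 9.53 ± 0.13 (adjusted p = 2.2e-04). Its differences at E18 (−1.10, adjusted p = 0.230) and E15 (−0.61, adjusted p = 0.456) missed the threshold. With only the arrays of the groups compared, the Trp63 difference passed at bladder E18 (adjusted p = 0.00845) and in proximal stomach (adjusted p = 0.00328), and with the mean of its probe sets it passed in proximal stomach (1.01, adjusted p = 0.00117). Wild-type levels were 7.12 ± 0.12 in distal stomach, 6.40 ± 0.05 in large intestine and 5.71 ± 0.05 in small intestine. The position of these probe sets relative to the deletion is not given, so their level checks nothing about the allele.

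Knockout proximal stomach lost cornified envelope genes and gained genes of simple epithelium. The proximal stomach of the mouse is lined by a stratified squamous epithelium. Genes of its outer layers fell close to the array's floor: Lce3f from 14.99 ± 0.09 to 4.90 ± 0.78, Hrnr from 13.56 ± 0.11 to 4.13 ± 0.50, and Flg, which encodes filaggrin, from 12.81 ± 0.21 to 3.95 ± 0.18. Krt5 and Krt14, the keratins of basal cells, changed by −5.80 (SE 0.19, adjusted p = 1.4e-15) and −5.54 (SE 0.46, adjusted p = 4.9e-09). Spink4 and Agr2, which are expressed in mucus-secreting cells, rose by 7.55 (SE 0.36, adjusted p = 5.7e-13) and 7.01 (SE 0.22, adjusted p = 5.0e-16). Other large decreases were those of Lce3a (−9.60), the desmosome protein gene Cdsn (−9.08), Serpinb3a (−8.86), Lce1a1 (−8.85), Lce1d (−8.75), Lce1f (−8.72) and the defensin gene Defb4 (−8.72). Other large increases were those of Alox15 (7.21), the mucin gene Muc4 (6.52), Calcb (6.43), Cd177 (6.42), Lrrc26 (6.25), Adh7 (6.20), Krt20 (5.92) and Aox3 (5.87). With limma, 4448 of 13613 genes passed, 2464 higher and 1984 lower, and 1612 of them changed at least 2-fold. With a covariate for RNA quality, which goes with genotype here, 2059 passed, 1981 of them among the 4448. Both knockout arrays lay outside the wild-type range for 63.8% of genes, against 33.3% by chance.

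**Figure D1:**
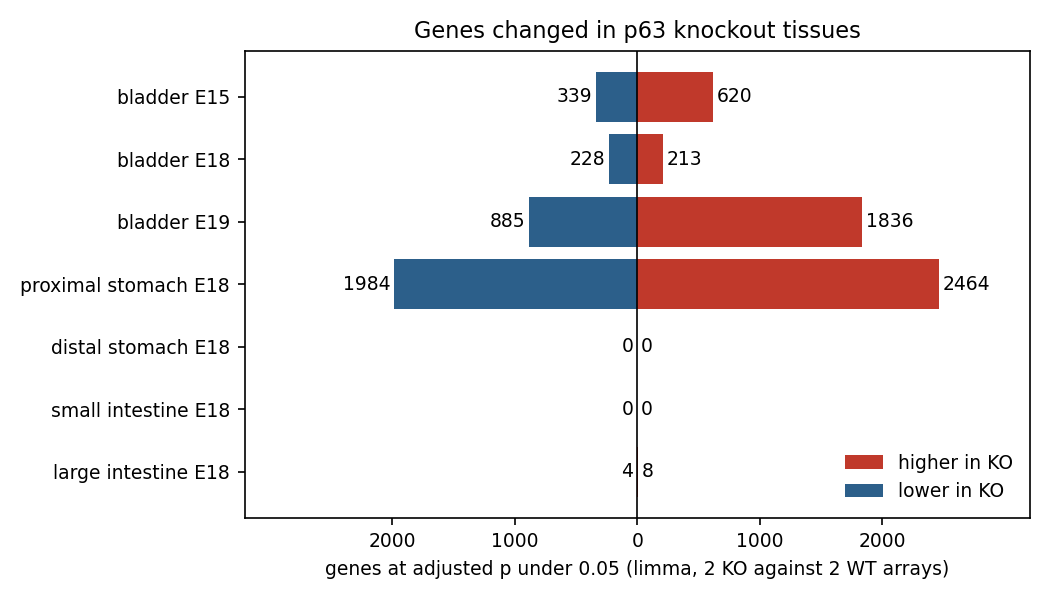
Number of genes at an adjusted p under 0.05 in each tissue and stage, those higher in the knockout to the right and those lower to the left. Proximal stomach had the most at 4448, bladder 441 to 2721, large intestine 12, and distal stomach and small intestine had 0.

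**Figure D2:**
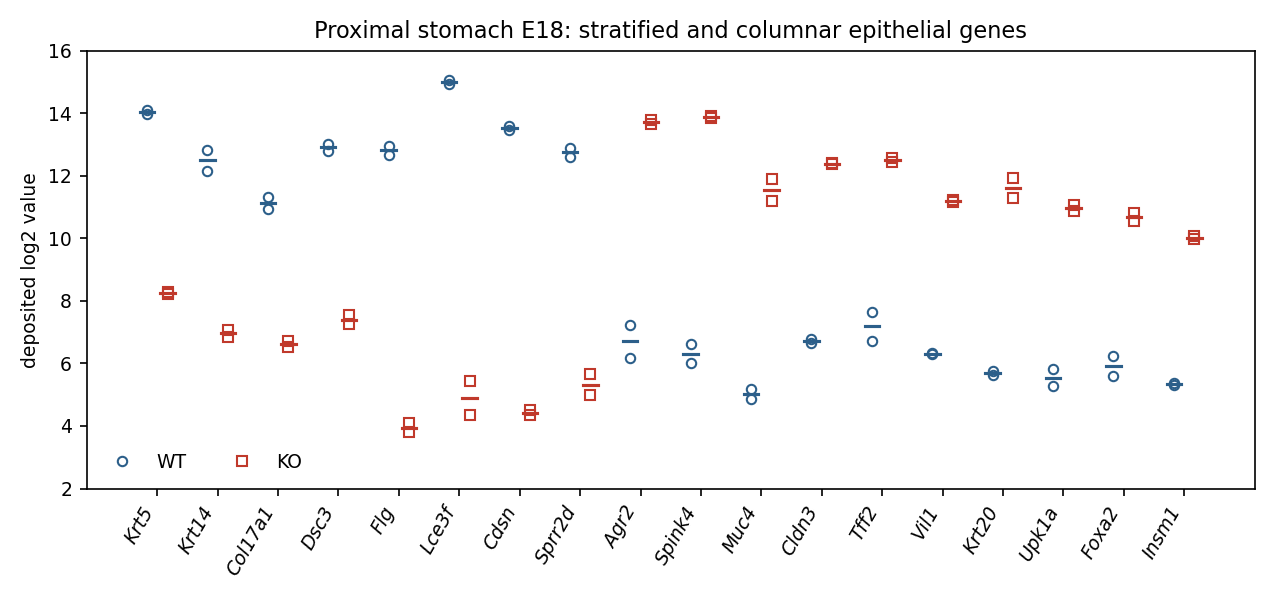
Level on the log2 scale of 18 genes in proximal stomach at E18, with a point for each array and a line at the mean of the 2 arrays of a genotype. Krt5, Krt14, Col17a1, Dsc3 and the cornified envelope genes are lower in both knockout arrays, and Agr2 to Insm1 are higher.

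The gene lists showed which epithelial genes moved in proximal stomach. Of 33 measured squamous and cornified genes 27 fell and 0 rose, 27 and 0 adjusted over the list alone, among them Crct1 (−8.66), Sprr1b (−8.51) and Sprr2d (−7.43). The list's mean was −3.42 (camera adjusted p = 4.1e-22, adjusted p = 0.0103 with an estimated correlation). Of 26 basal genes 14 fell and 1 rose, 14 and 2 adjusted over the list alone, with Dsc3 at −5.52 and the hemidesmosome collagen gene Col17a1 at −4.50 (camera adjusted p = 1.9e-06, adjusted p = 0.00978 with an estimated correlation). Of 24 simple epithelial genes 20 rose, 21 adjusted over the list alone, led by Muc4, Agr2, Cldn3 (5.68) and Car4 (4.28), at a camera p of 4.6e-14 and an adjusted p = 0.0454 with an estimated correlation. Urothelial genes rose too, 12 of 19 with 2 lower, 13 and 2 adjusted over the list alone. They included the uroplakin genes Upk1a (5.42, from 5.55 ± 0.38 to 10.97 ± 0.12) and Upk2 (5.31), and Snx31 (4.40). This list passed at the preset correlation (camera adjusted p = 1.2e-04), with an adjusted p = 0.0733 with an estimated correlation.

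Glandular and endocrine genes rose in smaller number in proximal stomach. Of 21 gastric glandular genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone. Tff2 rose by 5.32 (SE 0.26), Tff1 by 3.69 (SE 0.54) and Ctse by 2.69 (SE 0.52), while the water channel gene Aqp5 changed by −3.24 (SE 0.25). Camera gave adjusted p = 0.0395 for this list, and adjusted p = 0.819 with an estimated correlation. Without knockout replicate 2 the gastric list's p was 0.36 and without wild-type replicate 1 it was 0.145. Of 15 enteroendocrine genes 7 rose, 8 adjusted over the list alone, among them the transcription factor gene Insm1 (4.68) and the granule protein genes Chga (2.95) and Scg2 (2.42), at camera adjusted p = 0.0234 and adjusted p = 0.645 with an estimated correlation. With the filter at the 75th percentile the gastric and enteroendocrine lists no longer passed (adjusted p = 0.0858 and 0.472). Of 16 skeletal muscle genes 4 fell, 6 adjusted over the list alone, with Myog at −3.83 and Myod1 at −1.75 (camera adjusted p = 0.0106, adjusted p = 0.819 with an estimated correlation). The skeletal muscle list gave adjusted p = 0.0712 without wild-type replicate 1 and adjusted p = 0.129 with the filter at the 75th percentile. Proliferation genes were lower, 7 of 22, 7 adjusted over the list alone, with a mean of −0.32 (camera adjusted p = 0.0104, adjusted p = 0.912 with an estimated correlation). Its call ended without knockout replicate 2 (−0.14) or wild-type replicate 2. Mki67 fell by 0.63 (SE 0.16, adjusted p = 0.0037), by 0.37 without knockout replicate 2 (adjusted p = 0.127) and by 0.50 with the actin covariate (adjusted p = 0.203).

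Signalling and patterning genes moved in both directions in proximal stomach, and none of their lists passed camera. Of 17 Wnt pathway genes 6 rose and 5 fell, 7 and 5 adjusted over the list alone: the secreted inhibitor genes Wif1 (4.78) and Notum (4.13) and Lef1 (2.28) rose, and Wnt10a fell by 3.71. Of 12 Notch pathway genes 2 rose and 4 fell, 3 and 4 adjusted over the list alone, with Jag2 at −1.85, Nrarp at −1.58 and Notch1 at −1.58. Hedgehog genes rose in 5 of 10 cases, 5 adjusted over the list alone, among them Ihh (2.51) and its receptor's gene Ptch1 (0.73). Of 22 patterning factors 4 rose, 4 adjusted over the list alone, including Foxa2 (4.77, from 5.92 ± 0.46 to 10.69 ± 0.17) and Foxa3 (3.04). Intestinal genes went both ways: 10 of 38 rose and 4 fell, 10 and 4 adjusted over the list alone, with Vil1 (4.89) and Hnf4a (3.27) higher and Rbp2 lower (−5.51). Among 10 mesothelial genes 4 rose, Msln by 2.91, and 1 fell, 4 and 1 adjusted over the list alone. Of 13 p53 targets 5 rose and 3 fell, 5 and 4 adjusted over the list alone, with Phlda3 at −1.47. Mean and median differed in sign for the Wnt (0.28 and −0.26), Notch (−0.19 and 0.26), mesothelial (0.47 and −0.03), pancreas (0.26 and −0.02) and patterning lists (0.32 and −0.09). The median (0.20) and mean (0.03) of the immediate early and heat shock list were above 0 while camera's direction was down.

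None of the remaining lists of proximal stomach passed camera. Of 13 ciliated cell genes 3 rose, among them the dynein gene Dnaic1 (1.61, SE 0.35), and 2 fell, 3 and 2 adjusted over the list alone. Serpina1b changed by −4.80 (SE 0.35) as the 1 of 12 liver genes that passed, 1 adjusted over the list alone. Immune genes rose in 4 of 16 cases, 3 adjusted over the list alone. Fibroblast and matrix genes numbered 1 higher and 4 lower of 20, the same counts adjusted over the list alone, and smooth muscle genes 1 and 1 of 20 by both counts. Cardiac muscle genes fell in 3 of 6 cases, 3 adjusted over the list alone, and hypoxia and glycolysis genes in 4 of 13 cases, 4 adjusted over the list alone. Immediate early and heat shock genes numbered 1 higher and 4 lower of 14, and hindgut and colon genes 1 and 1 of 7, with the same counts adjusted over the list alone. Neuron and glia genes numbered 3 higher and 1 lower of 21, 1 and 0 adjusted over the list alone. Endothelial genes rose in 2 of 16 cases and erythroid genes in 1 of 6, 0 in both adjusted over the list alone. Of 10 pancreas genes 1 rose, 1 adjusted over the list alone. With limma 0 of 2 genes of the Wolffian duct, prostate and kidney list and 0 of 4 sex-linked genes passed, and also 0 adjusted over the list alone. The lists that camera did not call in proximal stomach had adjusted p-values between 0.143 and 0.993.

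In knockout bladder at E18 basal keratin genes were lower, and genes such as Tff3 and Guca2a were higher. Krt5 changed by −4.83 (SE 0.19, adjusted p = 1.2e-12), from 12.44 ± 0.38 to 7.61 ± 0.24. The goblet cell peptide gene Tff3 rose from 7.28 ± 0.22 to 11.76 ± 0.10 (4.49, SE 0.20, adjusted p = 6.3e-12), and Guca2a, which encodes guanylin, from 7.13 ± 0.16 to 11.85 ± 0.10 (4.73, SE 0.23). Nlrp10 had the largest increase at 5.71 (SE 0.51). Others were those of Anxa13 (4.21), Olfm4 (3.66), Reg4 (3.51), Fabp1 (3.04), Mptx1 (3.02), Sval1 (2.94) and the matrix protease gene Mmp7 (2.77). Decreases also included Krt15 (−3.97), Clca2 (−3.71), Muc15 (−3.69), Clca3a2 (−3.27), Dapl1 (−2.95), Edaradd (−2.84), Tns4 (−2.80), Ugt2b34 (−2.70) and Upk3bl (−2.68). With limma 441 genes passed, 213 higher and 228 lower, and 48.3% of them were higher, or 33.4% with median centring. Separated genes made up 49.3%, against 33.3% by chance.

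Single arrays decided part of the bladder E18 result. The count was 265 without knockout replicate 1, 203 without wild-type replicate 1 and 164 without wild-type replicate 2, and 716 with array weights and 291 with only the arrays of the groups compared. Krt15 was 10.22 ± 2.15 in the knockout and changed by −2.45 without knockout replicate 2 (adjusted p = 2.0e-04). The change of Clca3a2 was −5.29 without knockout replicate 1 and −1.25 without knockout replicate 2. Its call ended without wild-type replicate 1 or 2. Fabp1 lost its call without knockout replicate 1, wild-type replicate 1 or wild-type replicate 2, and with the mean of its probe sets (adjusted p = 0.0662). Upk3bl lost it without wild-type replicate 1. With only the arrays of the groups compared, Krt15 (adjusted p = 0.0751) and Clca3a2 (adjusted p = 0.21) no longer passed.

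Among the lists in bladder E18, 12 of 26 basal genes fell, 19 adjusted over the list alone, including Lama3 (−2.22, SE 0.35) and Krt14 (−2.13, SE 0.46). The basal list's mean was −1.19 (camera adjusted p = 5.8e-19, adjusted p = 5.1e-05 with an estimated correlation). Krt14 changed by −1.21 without wild-type replicate 1. Its call ended there, without knockout replicate 1 and with only the arrays of the groups compared (adjusted p = 0.107). Of 38 intestinal genes 9 rose, 12 adjusted over the list alone, among them Tff3, Guca2a, Fabp1 and Fcgbp (2.57, SE 0.29), with a mean of 0.80 (camera adjusted p = 4.1e-09, adjusted p = 0.0733 with an estimated correlation). The hindgut gene Lypd8 rose by 2.05 (adjusted p = 0.0053, and adjusted p = 0.0517 without wild-type replicate 1), and the mucous cell gene Agr2 by 1.57 (SE 0.22) from 11.75 ± 0.33. Squamous genes numbered 2 higher and 3 lower of 33, Lypd3 falling by 2.51, and that list did not pass (camera adjusted p = 0.4). Nor did the urothelial list, where 0 of 19 genes passed limma (camera adjusted p = 0.37).

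Some genes of the Hedgehog and Notch pathways were lower in knockout bladder E18. Hhip, a target of Hedgehog signalling, changed by −1.53 (SE 0.17), and 2 of 10 Hedgehog genes fell, 5 adjusted over the list alone (camera adjusted p = 4.8e-05, adjusted p = 0.403 with an estimated correlation). Jag2 (−1.83, SE 0.21), Nrarp (−1.25) and Notch1 (−0.95) were the 3 of 12 Notch pathway genes that fell, 4 adjusted over the list alone (camera adjusted p = 5.7e-04, adjusted p = 0.188 with an estimated correlation). Wnt10a fell by 2.62 (SE 0.38). Sox2 changed by −2.04 (adjusted p = 0.0051) and by −1.20 without knockout replicate 2. Its call ended there, without wild-type replicate 2 and with only the arrays of the groups compared (adjusted p = 0.111). Foxa3 rose by 1.78 (SE 0.25). Proliferation genes fell in 6 of 22 cases, 15 adjusted over the list alone, with a mean of −0.45 (camera adjusted p = 1.1e-12, adjusted p = 0.422 with an estimated correlation), or −0.25 without knockout replicate 2. Of 24 simple epithelial genes 2 rose, 6 adjusted over the list alone (camera adjusted p = 0.00348, adjusted p = 0.696 with an estimated correlation), and this call ended without knockout replicate 1 (adjusted p = 0.183).

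Lists of nerve, muscle, immune and endocrine cells were higher in knockout bladder E18 by camera at the preset correlation, and 1 array carried most of these calls. Of 21 neuron and glia genes 3 rose, 8 adjusted over the list alone, with a mean of 0.75 that fell to 0.08 without knockout replicate 1 (camera adjusted p = 5.6e-06, adjusted p = 0.752 with an estimated correlation, adjusted p = 0.5 without that array) and to 0.40 without wild-type replicate 1. For 16 skeletal muscle genes the mean was 0.86, with 4 higher adjusted over the list alone, and 0.28 without knockout replicate 1 (camera adjusted p = 0.00491, adjusted p = 0.798 with an estimated correlation, adjusted p = 0.243 without that array). For 16 immune genes the mean was 0.47, with 2 higher adjusted over the list alone (camera adjusted p = 1.9e-04, adjusted p = 0.807 with an estimated correlation), and p was 0.054 without knockout replicate 2. For 15 enteroendocrine genes the mean was 0.43, with 2 higher adjusted over the list alone (camera adjusted p = 0.0252, adjusted p = 0.645 with an estimated correlation), and without knockout replicate 1 it was 0.17 (adjusted p = 0.366). With the filter at the 75th percentile p was 0.472 for skeletal muscle and 0.213 for enteroendocrine genes, and with only the arrays of the groups compared it was 0.0693 for the latter.

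At E19 knockout bladder had lower basal keratins, and genes such as Nlrp10, Guca2a and Mcm2 were higher. Krt5 changed by −5.01 (SE 0.19, adjusted p = 3.1e-13), Krt15 by −4.78 (SE 0.54) and Krt14 by −3.14 (SE 0.46). Nlrp10 rose by 5.28 (SE 0.51), from 5.24 ± 0.23 to 10.52 ± 0.14, Guca2a by 4.41, Tff3 by 4.35, the goblet cell gene Clca1 by 4.20 and Sval1 by 3.75. Mcm2, Mcm5 and Mcm3, which encode parts of the replicative helicase, rose by 1.63 (SE 0.20), 1.46 (SE 0.23) and 1.12 (SE 0.21). Clca3a2 (−4.23), Defb1 (−3.57), Wnt10a (−3.52), Lypd3 (−2.60) and Hhip (−1.99) fell. Agr2 rose by 3.24 (SE 0.22), from 9.06 ± 0.02 to 12.30 ± 0.06. With limma 2721 genes passed, 1836 higher and 885 lower. Separated genes made up 64.6%, against 33.3% by chance. Leaving out knockout replicate 1, knockout replicate 2 or wild-type replicate 1 gave counts of 1435, 1364 and 1666. With median centring the median change of all genes was 0.12.

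Of the lists at E19, the basal one fell in 15 of 26 genes with 1 higher, 16 and 2 adjusted over the list alone (camera adjusted p = 2.4e-14, adjusted p = 1.5e-04 with an estimated correlation). Intestinal genes rose in 13 of 38 cases, 13 adjusted over the list alone (camera adjusted p = 6.9e-04, adjusted p = 0.422 with an estimated correlation). Proliferation genes rose in 16 of 22 cases, 19 adjusted over the list alone, with a mean of 0.71 (camera adjusted p = 2.1e-09, adjusted p = 0.622 with an estimated correlation). Immediate early genes rose in 8 of 14 cases with 1 lower, 8 and 1 adjusted over the list alone, Fos by 1.99 (SE 0.41), at camera adjusted p = 0.0433 and adjusted p = 0.824 with an estimated correlation. Leaving out knockout replicate 1, wild-type replicate 1 or wild-type replicate 2 gave adjusted p = 0.0698, 0.0554 and 0.0971 for that list, and median centring, the filter at the 75th percentile, limma without a trend and array weights gave p between 0.0579 and 0.0959. Hedgehog genes fell in 4 of 10 cases, 4 adjusted over the list alone (camera adjusted p = 0.0429, adjusted p = 0.819 with an estimated correlation). Its p was 0.0571 without knockout replicate 1, 0.0695 without wild-type replicate 2, 0.0568 with the replicate block and 0.0526 to 0.168 with quantile normalization, no filter, the filter at the 75th percentile, the mean of probe sets or no trend. Lists without a camera call held genes that passed, such as Nrarp (−1.17) of the Notch pathway, Hk2 (1.40) of glycolysis, Coro1a (1.23) of immune cells and Uchl1 (1.28) of neurons.

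At E15 knockout bladder had higher levels of simple epithelial genes and a modest decrease of Krt5. Spint1, a protease inhibitor gene of epithelia, rose by 1.35 (SE 0.11, adjusted p = 9.7e-07), Esrp2 by 1.24 (SE 0.15), Klf5 by 1.25 (SE 0.13) and Snx31 by 1.61 (SE 0.26). Krt5 changed by −1.24 (SE 0.19, adjusted p = 6.8e-04), from 8.30 ± 0.25 to 7.06 ± 0.20. The largest increases among named genes were Fabp1 (3.06), Prph (2.57), Calcb (2.16), L1cam (2.06) and Mybpc1 (2.06). The largest decreases were Krt15 (−2.04), Sox2 (−1.69), Peg10 (−1.69), Anxa8 (−1.59) and Thbs1 (−1.59). With limma 959 genes passed, 620 higher and 339 lower. Separated genes made up 55.3%, against 33.3% by chance.

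The E15 count depended on single arrays, and most calls ended with a covariate for RNA quality. The count was 211 without knockout replicate 1, 1783 without knockout replicate 2, 126 without wild-type replicate 1 and 452 without wild-type replicate 2, and 514 with only the arrays of the groups compared. The 3' minus 5' signal of actin, which grows as RNA degrades, was 1.33 and 1.12 in the knockout arrays and 0.69 and 0.78 in the wild-type arrays, so it goes with genotype here. With it as a covariate, 3 genes passed: the median SE went from 0.179 to 0.326 and the median size of the called changes from 0.69 to 0.49, and 939 of the 959 kept their sign. Spint1 then had a change of 1.06 (adjusted p = 0.0596) and Krt5 of −1.40 (adjusted p = 0.346), and none of the genes named here for E15 kept its call. Without 1 array, L1cam, Krt5, Spint1, Esrp2, Klf5 and Snx31 kept their calls in each of the 4 cases. Without knockout replicate 1 the calls of Fabp1, Krt15, Sox2, Peg10 (−0.81) and Thbs1 ended. Without knockout replicate 2 those of Mybpc1 (0.91) and Anxa8 ended, and Peg10 changed by −2.56, while Mybpc1 rose by 3.21 without knockout replicate 1. Wild-type replicate 1 was needed for the calls of Fabp1, Prph, Calcb, Mybpc1, Krt15, Sox2, Peg10, Anxa8 and Thbs1. Wild-type replicate 2 was needed for Fabp1, Mybpc1, Krt15, Sox2, Peg10 and Anxa8. With only the arrays of the groups compared Mybpc1 (adjusted p = 0.0876) and Peg10 (adjusted p = 0.0699) no longer passed, and with robust priors Krt15 (adjusted p = 0.0516) did not.

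The simple epithelial and urothelial lists passed camera at E15 with both correlations, and no list was run with the actin covariate. Simple epithelial genes rose in 15 of 24 cases, 18 adjusted over the list alone, with a mean of 0.66 (camera adjusted p = 2.1e-14, adjusted p = 0.0454 with an estimated correlation). Urothelial genes rose in 6 of 19 cases, 13 adjusted over the list alone, with a mean of 0.76 (camera adjusted p = 5.7e-07, adjusted p = 0.0196 with an estimated correlation). Squamous genes rose in 6 of 33 cases, 7 adjusted over the list alone, Evpl by 1.54. That list stood at the threshold (camera adjusted p = 0.05, adjusted p = 0.824 with an estimated correlation): p was 0.0684, 0.104 and 0.0883 without knockout replicate 1, knockout replicate 2 and wild-type replicate 2, 0.0593 with the replicate block, and 0.0622 to 0.081 with quantile normalization, median centring or no trend. Basal genes numbered 2 higher and 3 lower of 26, 4 and 5 adjusted over the list alone, and did not pass camera (adjusted p = 0.339). Vil1 of the intestinal list rose by 1.35 (SE 0.22). Hedgehog genes fell in 1 of 10 cases, 2 adjusted over the list alone (camera adjusted p = 0.0211, adjusted p = 0.759 with an estimated correlation), and p was 0.148 without knockout replicate 2 and 0.094 without wild-type replicate 1. Notch genes fell in 2 of 12 cases, 2 adjusted over the list alone (camera adjusted p = 0.00953, adjusted p = 0.403 with an estimated correlation), with adjusted p = 0.053 without knockout replicate 2.

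Nerve and muscle markers rose in the same E15 arrays. Of 21 neuron and glia genes 8 rose, 13 adjusted over the list alone, among them Prph and Stmn2 (1.59), with a mean of 0.99 (camera adjusted p = 6.3e-06, adjusted p = 0.752 with an estimated correlation). Stmn2 lost its call without wild-type replicate 1, and the list, at 0.71, without knockout replicate 2. Skeletal muscle genes rose in 4 of 16 cases, 4 adjusted over the list alone, Tnni2 by 1.35 (SE 0.22), and their mean of 1.16 became 0.42 without knockout replicate 2 (camera adjusted p = 1.6e-04, adjusted p = 0.645 with an estimated correlation, adjusted p = 0.5 without that array). Mesothelial genes rose in 3 of 10 cases, 4 adjusted over the list alone, Upk3b by 0.80 (camera adjusted p = 0.0101, adjusted p = 0.403 with an estimated correlation), with adjusted p = 0.124 without knockout replicate 2.

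Averaged over the 3 bladder stages, Krt5 and Krt15 fell most and Nlrp10 rose most. Krt5 changed by −3.69 (SE 0.11, adjusted p = 2.8e-15) and Krt15 by −3.60 (SE 0.31). Nlrp10 rose by 4.12 (SE 0.30), Anxa13 by 2.998 (SE 0.14), Fabp1 by 2.88, Clca1 by 2.85 and the stem cell marker gene Olfm4 by 2.54. The other named increases were those of S100a8 (2.18), S100a9 (2.16), Agr2 (1.79), Sgpp2 (1.77) and Fam183b (1.68). The other named decreases were those of Muc15 (−2.52), Pm20d1 (−2.26), Defb1 (−2.26), Wnt10a (−2.18), Dapl1 (−2.06), Tns4 (−1.98), Upk3bl (−1.94) and Edaradd (−1.90). With the actin covariate S100a9 rose by 1.31 and no longer passed (adjusted p = 0.0704). With limma 2857 genes passed, 1900 higher and 957 lower. Genes separated the same way at each stage numbered 1598, or 11.7% against 0.926% by chance. The count was 1848 without knockout E15 replicate 1, 1840 without wild-type E15 replicate 1, 1238 without the 4 E19 arrays and 1185 with the actin covariate.

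**Figure D3:**
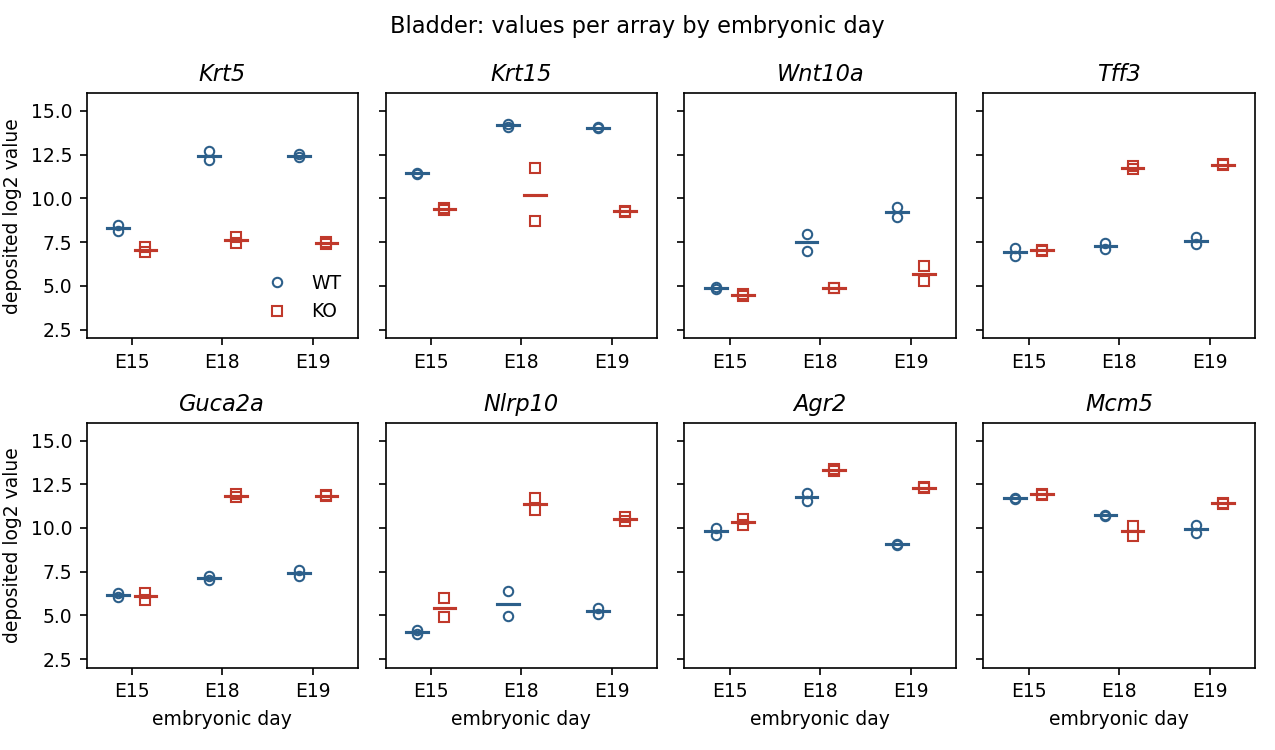
Level on the log2 scale of 8 genes in bladder at E15, E18 and E19, with a point for each array and a line at the mean of each genotype and stage. Both knockout arrays lie below the wild type for Krt5 and above it for Nlrp10 at each stage, and Tff3 and Guca2a part from the wild type at E18 and E19.

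In the bladder mean, 17 of 26 basal genes fell and 1 rose, 18 and 1 adjusted over the list alone. Simple epithelial genes rose in 13 of 24 cases, 15 adjusted over the list alone, intestinal genes in 14 of 38, 14 adjusted over the list alone, and urothelial genes in 8 of 19 with 1 lower, 10 and 1 adjusted over the list alone. Hedgehog genes fell in 5 of 10 cases, 5 adjusted over the list alone, with Hhip at −1.35 (SE 0.10). Notch genes fell in 4 of 12 cases, 5 adjusted over the list alone, with Jag2 and Nrarp both at −0.96. Sox2 fell by 1.68 (SE 0.23) and Foxa3 rose by 1.25 (SE 0.15).

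The bladder stages shared more called genes than chance gives. E15 and E18 shared 89 genes higher and 20 lower, against 9.70 and 5.68 expected from the sizes of the lists (Fisher's exact test, two-sided, adjusted over all direction pairs, adjusted p = 2.4e-62 and 2.2e-06). E18 and E19 shared 123 higher and 115 lower, against 28.7 and 14.8 (adjusted p = 6.0e-52 and 1.6e-74). All 3 stages shared 59 genes higher, such as Vil1, Spint1, Anxa13 and Fabp1, and 15 lower, such as Krt5, Krt15 and Sox2. Proximal stomach and bladder E18 shared 89 higher and 87 lower, against 38.6 and 33.2 (adjusted p = 2.6e-15 and 4.9e-18). With bladder E19 proximal stomach shared 359 higher against 332 expected (adjusted p = 0.106, unadjusted exact p = 0.0842) and 163 lower against 129 (adjusted p = 0.0016).

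Distal stomach and small intestine showed no gene past the threshold. In distal stomach 0 genes passed limma, and 528 had an unadjusted p under 0.05. In small intestine 0 passed, and 626 had an unadjusted p under 0.05. No other tool was run for these counts. Krt20 and Spink4, which rose in proximal stomach, had values of −1.47 and −1.08 in distal stomach and missed the threshold. Separated genes made up 27.7% in distal stomach and 41.4% in small intestine, against 33.3% by chance. The distal stomach count was 1 without knockout replicate 1, 5 without knockout replicate 2 and 252 without wild-type replicate 2. The small intestine count was 2 without wild-type replicate 1 and 14 without wild-type replicate 2. Covariates for Xist and Eif2s3y gave 1 gene in each of these tissues.

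Lists moved by small amounts in distal stomach, with 9 called at the preset correlation and 0 with an estimated one. The means were −0.43 for gastric glandular genes (camera adjusted p = 3.0e-05, adjusted p = 0.409 with an estimated correlation; −0.14 without wild-type replicate 1), −0.34 for intestinal genes (adjusted p = 1.4e-06, adjusted p = 0.182 with an estimated correlation) and −0.91 for liver genes (adjusted p = 9.0e-06, adjusted p = 0.403 with an estimated correlation). Intestinal genes lost the call without knockout replicate 2 and averaged −0.13 without wild-type replicate 1, and liver genes lost it at −0.29 without wild-type replicate 2. Hindgut genes (−0.38, adjusted p = 0.05, adjusted p = 0.476 with an estimated correlation) lost it in each of the 4 leave-outs and with quantile normalization, median centring, the filter at the 75th percentile, the mean of probe sets or no trend (p from 0.0622 to 0.11). Enteroendocrine genes (−0.26, adjusted p = 0.0429, adjusted p = 0.737 with an estimated correlation) lost it without knockout replicate 1, knockout replicate 2 or wild-type replicate 1 (0.02), and with each of 7 other alternatives (p from 0.0563 to 0.0914). Proliferation genes averaged 0.23 (adjusted p = 4.3e-07, adjusted p = 0.751 with an estimated correlation, and 0.05 at adjusted p = 0.484 without wild-type replicate 1). Immediate early genes averaged 0.61 (adjusted p = 1.2e-05, adjusted p = 0.422 with an estimated correlation, and 0.09 at adjusted p = 0.876 without knockout replicate 1). Notch genes averaged 0.19 (adjusted p = 0.0199, adjusted p = 0.422 with an estimated correlation), with 0.12 at adjusted p = 0.125 without knockout replicate 2 and 0.11 at adjusted p = 0.168 without wild-type replicate 1. Hedgehog genes averaged 0.19 (adjusted p = 0.0356, adjusted p = 0.802 with an estimated correlation), with 0.05 at adjusted p = 0.485 without knockout replicate 2, adjusted p = 0.0514 without a trend, and the opposite direction without wild-type replicate 1 (adjusted p = 0.911).

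In small intestine 6 lists passed at the preset correlation and 0 with an estimated one. Gastric glandular genes averaged −0.37 (camera adjusted p = 5.4e-05, adjusted p = 0.422 with an estimated correlation, and −0.03 at adjusted p = 0.464 without wild-type replicate 2) and proliferation genes 0.25 (adjusted p = 1.8e-06, adjusted p = 0.752 with an estimated correlation, and 0.11 without wild-type replicate 1). Intestinal genes averaged −0.13 (adjusted p = 0.00159, adjusted p = 0.473 with an estimated correlation), with −0.04 in both cases without knockout replicate 1 (adjusted p = 0.0774) or wild-type replicate 1 (adjusted p = 0.211). Neuron genes averaged 0.34 (adjusted p = 0.0364, adjusted p = 0.937 with an estimated correlation), with adjusted p = 0.144 without the same knockout array, 0.20 at adjusted p = 0.273 without the same wild-type array, and adjusted p = 0.0991 with the mean of probe sets and 0.0563 without a trend. Hedgehog genes averaged 0.31 (adjusted p = 0.0429, adjusted p = 0.819 with an estimated correlation), with adjusted p = 0.156 without knockout replicate 1, 0.12 at adjusted p = 0.632 without wild-type replicate 1 and adjusted p = 0.0563 without a trend. Squamous genes averaged −0.09 (adjusted p = 0.0429, adjusted p = 0.824 with an estimated correlation), with −0.02 at adjusted p = 0.222 without knockout replicate 1, −0.01 at adjusted p = 0.277 without wild-type replicate 1, and adjusted p = 0.0884 to 0.245 with median centring, no filter or the filter at the 75th percentile.

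Knockout large intestine had 12 genes past the threshold, and the 8 that rose encode proteins of the cornified envelope or of squamous cells. Lce3f rose from 5.23 ± 1.34 to 9.76 ± 1.20 (4.53, SE 0.57, adjusted p = 5.1e-04) and Sprr2d from 5.18 ± 0.12 to 7.84 ± 0.41 (2.66, SE 0.25, adjusted p = 7.7e-06). Hrnr rose by 3.71 (SE 0.56), Asprv1 by 2.99 (SE 0.48), Krtdap by 2.97 (SE 0.49), Lor by 2.85 (SE 0.52) and Sprr1b by 2.29 (SE 0.40). Sprr2h, named after its values were seen, was the other. Dsc3 fell from 8.83 ± 0.50 to 6.01 ± 0.24 (−2.82, SE 0.26), and the intestinal transport and enzyme genes Slc7a9 (−2.11), Iyd (−1.48) and Alpi (−1.44) fell too. With limma 8 were higher and 4 lower, and 665 genes had an unadjusted p under 0.05. Separated genes made up 27.0%, against 33.3% by chance.

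The large intestine calls rest on few arrays. Knockout replicate 2 exceeded knockout replicate 1 for all 8 genes that rose, with Hrnr at 9.21 and 5.997. Without knockout replicate 2, Hrnr rose by 2.10, Asprv1 by 1.69, Krtdap by 1.53, Lor by 1.83 and Sprr1b by 1.28. The calls of Lor, Sprr1b and Iyd then ended. Without wild-type replicate 1 the calls of Hrnr, Asprv1, Krtdap, Lor, Sprr1b, Slc7a9 (−1.34), Iyd and Alpi ended. Without knockout replicate 1 those of Slc7a9 and Alpi ended. Lce3f, Sprr2d and Dsc3 kept their calls in each of the 4 cases. The count was 58 without knockout replicate 1, 4 without wild-type replicate 1 and 121 without wild-type replicate 2. With only the arrays of the groups compared, 0 genes passed limma and the named genes had p between 0.745 and 0.999. Covariates for Xist and Eif2s3y gave 38 genes, and the replicate block gave 19, with adjusted p = 0.0762 for Alpi. Quantile normalization gave adjusted p = 0.063 for Alpi, array weights gave adjusted p = 0.0764 for Lor, 0.127 for Iyd and 0.28 for Alpi, and Lor had adjusted p = 0.0658 without a trend and 0.0589 without the E19 arrays.

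**Figure D4:**
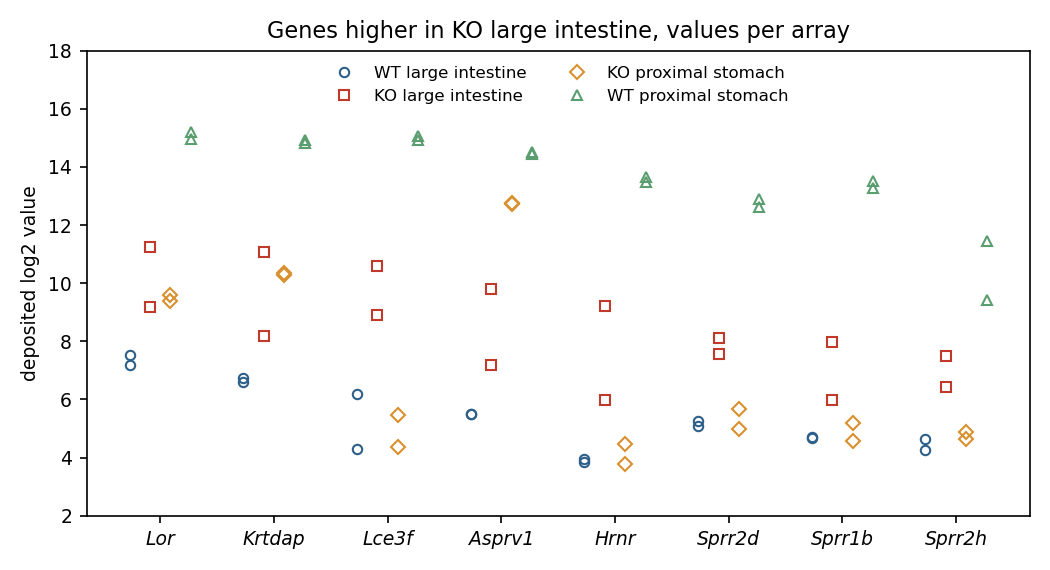
Level on the log2 scale of the 8 genes that rose in knockout large intestine, in large intestine and proximal stomach of both genotypes at E18, with a point for each array. Each gene lies higher in both knockout than in both wild-type large intestine arrays, and wild-type proximal stomach lies above all of these.

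Of 33 squamous genes in large intestine 4 rose, 9 adjusted over the list alone, with a mean of 0.52 (camera adjusted p = 3.5e-11, adjusted p = 0.0772 with an estimated correlation) and 0.25 without knockout replicate 2. Of 26 basal genes 1 fell, Dsc3. Intestinal genes averaged −0.40, with 1 of 38 lower, 3 adjusted over the list alone (adjusted p = 2.9e-06, adjusted p = 0.191 with an estimated correlation, adjusted p = 0.181 without knockout replicate 1), and −0.25 without wild-type replicate 1. Immune genes averaged −0.56, with 3 of 16 lower adjusted over the list alone (adjusted p = 7.4e-10, adjusted p = 0.422 with an estimated correlation), −0.16 without knockout replicate 2 (adjusted p = 0.0506) and −0.36 without wild-type replicate 1. Fibroblast genes averaged −0.21 (adjusted p = 0.00433, adjusted p = 0.834 with an estimated correlation), with adjusted p = 0.192 without knockout replicate 1 and 0.359 without wild-type replicate 2. Endothelial genes averaged −0.36 (adjusted p = 0.00258, adjusted p = 0.834 with an estimated correlation), with adjusted p = 0.388 without wild-type replicate 2 and a mean of 0.03 without knockout replicate 2 (adjusted p = 0.554). Mesothelial genes averaged −0.36 (adjusted p = 0.00126, adjusted p = 0.194 with an estimated correlation, and −0.22 at adjusted p = 0.495 without knockout replicate 1) and proliferation genes 0.17 (adjusted p = 2.2e-06, adjusted p = 0.755 with an estimated correlation, and 0.04 at adjusted p = 0.134 without wild-type replicate 1).

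**Figure D5:**
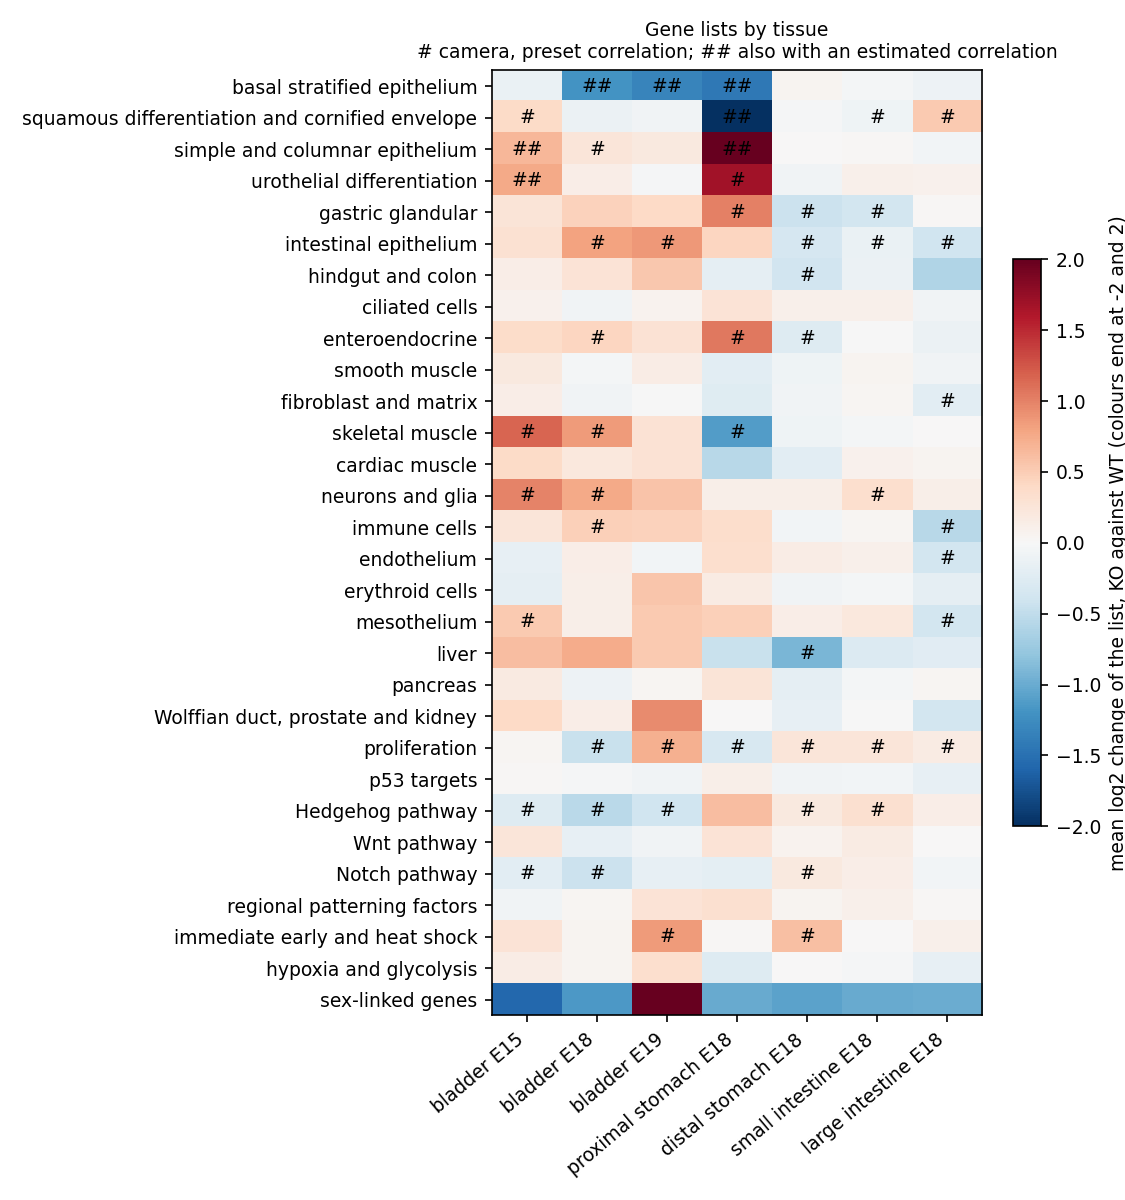
Mean change on the log2 scale of each of the 30 gene lists in the 7 tissues and stages, as a colour that ends at −2 and 2. A sign marks the 53 of 210 means that passed camera at the preset correlation, and a doubled sign the 7 that also passed with an estimated one.

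Averaged over all 7 tissues and stages, Defb1 fell by 1.96 (SE 0.11, adjusted p = 1.9e-10), and the claudin gene Cldn23 rose by 0.65 (SE 0.06, adjusted p = 6.8e-08) and Jrk by 0.35 (SE 0.07, adjusted p = 0.0013). These 3 genes were the ones separated the same way in each of the 7, or 0.0220% of genes. The 7.1e-04% by chance takes the tissues as independent. Replicate numbers pair wild-type gut arrays, so that chance share and the p-values here may be too small. With limma 1870 genes passed, 1215 higher and 655 lower, and 1221 without the 4 bladder E19 arrays.

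The knockout changes of proximal stomach differed from those of distal stomach, its neighbour. Spink4 rose by 7.55 in proximal stomach against a value of −1.08 in distal stomach, a difference of 8.64 (SE 0.51, adjusted p = 5.4e-11). Hrnr differed by −9.42, but at 3.81 in wild-type distal stomach it could hardly fall there. With limma 2618 genes differed, 1403 with a higher change in proximal stomach and 1215 with a lower one.

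Between bladder E18 and proximal stomach some genes moved in opposite directions. Nlrp10 rose by 5.71 in bladder and changed by −8.07 in proximal stomach, a difference of 13.79 (SE 0.72, adjusted p = 9.0e-12) whose size the array's floor limits. Upk3bl changed by −2.68 in bladder and by 5.08 in proximal stomach (difference −7.76, SE 0.70, adjusted p = 4.5e-08), and S100a3 by −2.50 and 4.38 (difference −6.88, SE 0.43, adjusted p = 1.4e-10). Lce3f, near the floor in wild-type bladder, differed by 10.33. With limma 3108 genes differed, 1420 higher and 1688 lower in bladder.

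The knockout changes of bladder differed between E15 and E18 for few genes, and this was not run with the actin covariate, which goes with genotype at E15. Krt5 changed by −1.24 at E15 and −4.83 at E18 (difference −3.60, SE 0.27, adjusted p = 8.3e-08). Guca2a and Tff3 differed by 4.82 (SE 0.33, adjusted p = 1.9e-08) and 4.38, and had values of −0.09 and 0.11 at E15. Reg4 differed by 3.92. With limma 83 genes differed, 31 higher and 52 lower at E18, so 37.3% were higher, or 26.9% with median centring, under which the median of all genes was −0.12. The count was 49 without knockout E15 replicate 1, 317 without knockout E15 replicate 2, 133 without knockout E18 replicate 1, 47 without knockout E18 replicate 2, 37 without wild-type E15 replicate 1, 46 without wild-type E18 replicate 1 and 53 without wild-type E18 replicate 2, and 131 with array weights. Reg4 lost its call without knockout E18 replicate 2, wild-type E15 replicate 2 or wild-type E18 replicate 1.

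The knockout change of some bladder genes differed between E18 and E19. Mcm5 had a value of −0.89 at E18 and rose by 1.46 at E19, a difference of 2.35 (SE 0.32, adjusted p = 2.6e-04). Edn2, Fos, Dynap and Cxcl14 differed by 3.45, 2.43, −2.44 and −2.43. With limma 718 genes differed, 542 higher and 176 lower at E19, so 75.5% were higher, or 86.1% with median centring, under which the median of all genes was 0.14. The count was 464 without knockout E18 replicate 2, 333 without knockout E19 replicate 1, 350 without knockout E19 replicate 2, 315 without wild-type E18 replicate 2 and 471 without wild-type E19 replicate 1. Fos lost its call without each of these arrays in turn. Dynap lost it without knockout E19 replicate 1 or wild-type E18 replicate 2, and Cxcl14 with the mean of its probe sets (−1.68, adjusted p = 0.067).

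Signatures of wild-type regions asked whether knockout tissue took on the expression of another region. In knockout proximal stomach 25 of 85 genes of the distal stomach signature rose and 6 fell, with a mean of 0.57 (camera adjusted p = 0.0191, adjusted p = 0.428 with an estimated correlation). That mean was 0.44 without knockout replicate 2 (adjusted p = 0.118) and 0.51 without wild-type replicate 1 (adjusted p = 0.0617), and an 8-fold threshold gave 0.50 (adjusted p = 0.112). The bladder signature fell in 70 of 217 genes and rose in 23, with a mean of −0.61 (adjusted p = 1.1e-05, adjusted p = 0.33 with an estimated correlation). The intestine signature had 18 of 116 genes higher and 13 lower and a mean of −0.03 (adjusted p = 0.588). In knockout bladder E18 the intestine signature rose in 12 of 116 genes and fell in 1, with a mean of 0.36 (adjusted p = 0.00104, adjusted p = 0.33 with an estimated correlation). The distal stomach signature rose in 7 of 101 genes and fell in 1, with a mean of 0.33 (adjusted p = 5.1e-04, adjusted p = 0.33 with an estimated correlation). The proximal stomach signature fell in 40 of 414 genes and rose in 15, with a mean of −0.11 (adjusted p = 0.0317, adjusted p = 0.428 with an estimated correlation). It lost its call without knockout E18 replicate 2 (−0.06) or wild-type E18 replicate 1 (−0.07), with the 8-fold threshold (adjusted p = 0.112), median centring (adjusted p = 0.25), the filter at the 75th percentile (adjusted p = 0.178) and only the arrays of the groups compared (adjusted p = 0.1).

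Wild-type bladder gained muscle, urothelial and basal genes between E15 and E18. The muscle genes Ckm, Acta1 and Synm rose by 5.70 (SE 0.35, adjusted p = 6.3e-10), 5.60 (SE 0.53) and 5.37 (SE 0.43), and the embryonic globin genes Hbb-y and Hba-x fell by 5.82 and 3.63. Krt5 rose from 8.30 ± 0.25 to 12.44 ± 0.38 and Krt14 by 2.92. Of 26 basal genes 18 rose and 2 fell, of 19 urothelial genes 16 rose, of 33 squamous genes 16, of 24 simple epithelial genes 19 with 1 lower, and of 20 smooth muscle genes 15. Proliferation genes fell in 20 of 22 cases and endothelial genes in 9 of 16. Adjusted over the list alone these counts were 18 and 2, 16, 17, 19 and 1, 15, 21 and 9. With limma 6130 genes changed, 2333 higher and 3797 lower.

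Between E18 and E19 the wild-type bladder changed in more genes than between E15 and E18. Ces5a rose by 7.26 (SE 0.23, adjusted p = 6.8e-16), Xdh by 5.64, Serpina3n by 5.13 and Smr2 by 4.80, while Hba-a2, Peg10 and Sox11 fell by 6.16, 5.88 and 5.25. The cell division genes Birc5 and Mcm3 fell by 2.78 and 2.63 and the collagen gene Col1a1 by 2.07. Rpl37, a ribosomal protein gene, went from 4.98 ± 0.20 to 11.49 ± 0.02, Thoc1 from 12.99 ± 0.01 to 6.25 ± 0.17 and Man2c1os from 10.18 ± 0.06 to 4.59 ± 0.13. Proliferation genes fell in 20 of 22 cases, 21 adjusted over the list alone. With limma 8591 genes changed, 3684 higher and 4907 lower, so 42.9% were higher, or 57.3% with median centring, which moved the median of all genes from −0.08 to 0.15. The E19 arrays had medians of 7.48 to 7.53 and the others 7.73 to 7.86, so stage and a batch of arrays cannot be told apart here. Both wild-type E19 arrays expressed Xist, against 1 of the 2 at E18, so fetal sex was unbalanced too, and the strain, Balb/c by all labels, was not tested.

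Wild-type proximal and distal stomach differed in their epithelial genes. Hrnr, Lce3a, Lce3f, Cdsn and Sprr3 were higher in proximal stomach by 9.75 (SE 0.56, adjusted p = 6.4e-12), 9.49, 9.47, 9.38 and 9.23, the desmosome gene Pkp1 by 8.61 and Krt5 by 6.88. The gastrokine genes Gkn1 and Gkn2 differed by −9.96 (SE 0.72, adjusted p = 3.2e-10) and −9.01, Dmbt1 by −8.38, the intrinsic factor gene Cblif by −8.10 and Agr2 by −7.99. Squamous genes were higher in proximal stomach in 32 of 33 cases, and gastric glandular genes lower in 20 of 21 with 1 higher, 33 and, for the latter, 20 and 1 adjusted over the list alone. With limma 5504 genes differed, 2474 higher and 3030 lower in proximal stomach.

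Wild-type small and large intestine differed in absorptive and patterning genes. Lct, which encodes lactase, Apoc3, Apoa4, Leap2 and Clca4b were higher in small intestine by 8.80 (SE 0.29, adjusted p = 6.3e-15), 8.03, 7.95, 7.94 and 7.86. Hoxa10, Atp12a, the hormone gene Insl5, Hoxd10 and Hoxd13 differed by −7.76, −7.38, −7.35, −7.32 and −7.02, and Pyy by −2.65. With limma 5917 genes differed, 2659 higher and 3258 lower in small intestine.

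Sex-linked genes and RNA quality differed between groups. At E19 both knockout arrays expressed the Y-linked gene Eif2s3y (11.65 and 11.59) and both wild-type arrays expressed Xist (12.96 and 13.20), so genotype and fetal sex cannot be told apart within that stage. With the levels of Xist and Eif2s3y as covariates, estimated over all arrays, 2110 genes passed limma at E19. At E15 and E18 both knockout bladder arrays expressed Xist without Eif2s3y, while the wild type had 1 array of each kind. In proximal stomach the 3' minus 5' actin signal was 0.97 and 0.88 in wild type and 0.48 and 0.61 in the knockout. With the actin covariate 4432 of the 4448 called changes kept their sign. The median SE went from 0.179 to 0.277 and the median size of the called changes from 0.79 to 0.75. Probe sets of 1 gene were called in opposite directions for 13 genes at bladder E15, 54 at E19 and 19 in proximal stomach, of 6296 genes with several probe sets.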

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

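The 3 tests of explanations for the intestinal genes of knockout bladder were chosen after the result was seen, and the counts of differing genes were planned. The results here differ between tissues or stages by a test of the difference itself, or come from probe sets without a gene symbol. No group had more than 2 arrays, so no array was tested for lying apart from its group.

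The knockout change of 2618 genes differed between proximal and distal stomach by limma. The largest positive differences, proximal minus distal, were those of Spink4 (8.64), Krt20 (7.40), Agr2 (7.17), Alox15 (6.97) and Muc4 (6.91). The largest negative ones were those of Hrnr (−9.42), Lce3a (−9.37), Cdsn (−9.15), Lce3f (−8.91) and Lce1a1 (−8.86). These genes passed in proximal stomach and missed the threshold in distal stomach. Wild-type distal stomach had Hrnr (3.81), Lce3a (4.95), Cdsn (4.13) and Lce3f (5.52) near the floor, where a fall can hardly be measured. Agr2 (14.71) was near the top there.

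Between bladder E18 and proximal stomach 3108 genes differed. Nlrp10 differed by 13.79, Lce3f by 10.33, Lce3a by 9.54, Hrnr by 9.42 and Lce1a1 by 9.34. The cornified genes among these lay near the floor in wild-type bladder, where a fall can hardly be measured. Upk3bl differed by −7.76, Alox15 by −7.64, S100a3 by −6.88, Adh7 by −6.72 and Muc4 by −6.24.

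Between bladder E18 and E15 the change of 83 genes differed: Guca2a by 4.82, Tff3 by 4.38, Nlrp10 by 4.34, Reg4 by 3.92, Peg10 by 3.49, Krt5 by −3.60, Clca2 by −3.56, S100a3 by −3.18, Ugt2b34 by −2.83 and Pkp1 by −2.75. At E15 the RNA quality signal goes with genotype, and this difference was not run with the actin covariate. The count ranged from 37 to 317 when 1 array was left out.

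Between bladder E19 and E18 the change of 718 genes differed: Edn2 by 3.45, Lrr1 by 2.97, Fos by 2.43, Mcm5 by 2.35, Col4a4 by 2.30, Galnt15 by −2.52, Dynap by −2.44, Cxcl14 by −2.43, Naip5 by −2.38 and Ptx3 by −2.37. Within E19 genotype and fetal sex cannot be told apart. The count ranged from 315 to 687 when 1 array was left out.

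Of 4439 probe sets with no gene symbol or several that passed the filter, limma called 307 at bladder E15, 45 at bladder E18, 758 at bladder E19, 997 in proximal stomach, 3 in large intestine and 690 in the bladder mean. Their transcripts stay unnamed here.

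In knockout bladder E18, 12 genes of the intestine signature rose with a median of 2.46, and Guca2a and Tff3 led them. Intestinal tissue carried into the knockout samples would bring its other abundant transcripts too. A share of 4.98% large intestine, as implied by the 12 genes, would raise 54 signature genes by 1 or more on the log2 scale. Of these 81.5% stayed below the midpoint of that rise, and with small intestine 88.4% of 95. Taking the share from genes picked for rising inflates it, so a smaller share is not excluded. The 54 genes had a median rise of 0.20 against 1.73 implied, and the 95 genes 0.12 against 2.96. A share small enough for these medians would raise the 12 genes by less than was seen. These values argue against intestine like the wild type as the source of most of that rise. Loss of basal cells would raise the markers of the remaining cell types alike. The largest median among the urothelial, smooth muscle and fibroblast lists was 0.26, but these whole lists were set against 12 genes picked for rising. Neuron, skeletal muscle, immune and enteroendocrine lists rose at the preset correlation, though mostly through 1 array, so the medians do not decide this. Both knockout arrays at E18 and 1 of 2 wild-type arrays expressed Xist, while at E19 the sexes were reversed, so an effect of fetal sex would point the other way there. The 12 genes had a median change of 2.17 at E19, and 11 of them were higher by limma, Ccl9, named after its values were seen, being the exception at −0.50, which argues against fetal sex as the whole cause. A gain of secretory cells or of their genes within the bladder epithelium may account for the pattern and stays a hypothesis. A smaller share of intestine, for part of the rise, and tissue that no array here represents stay open.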

How the results depend on the processing

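The alternatives were planned except those with the E19 or E15 arrays left out and those with covariates, which were added after the data were seen. Of 376 counts under an alternative, 316 stayed within 1.5 times the reported count. Of 4962 values of named genes 4850 kept direction and side of the threshold, 109 lost the call, 3 gained it and 0 reversed. Of 795 list values 654 kept both, 139 lost the call and 2 reversed, and of 96 signature values 82 kept both and 14 lost the call. Quantile normalization, median centring, both filters, the mean of probe sets and both other variance models moved no count by more than 1.5 times. The cause of the changes below was not tested, except where the alternative itself uses fewer genes or arrays.

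Array weights gave 716 genes at bladder E18 and 131 for E18 against E15. With an estimated correlation 7 lists passed in place of 53, and 5 signatures lost the call at unchanged means: 0.57 for distal stomach and −0.61 for bladder in proximal stomach, and −0.11 for proximal stomach, 0.33 for distal stomach and 0.36 for intestine in bladder. The 8-fold threshold gave 0.50 for the distal stomach signature in proximal stomach and −0.10 for the proximal stomach signature in bladder. The latter also lost the call at −0.16 with median centring, and at −0.11 with the filter at the 75th percentile and with only the arrays of the groups compared.

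A minimum of 2-fold leaves fewer genes by construction: 231 at bladder E15, 196 at E18, 606 at E19, 1612 in proximal stomach, 186 in the bladder mean, 94 in the mean of 7, 1601 for proximal against distal stomach, 1683 for bladder E18 against proximal stomach and 363 for E19 against E18. In wild type it leaves 1673 for E18 against E15, 3902 for E19 against E18, 2349 for the stomach regions and 2301 for the intestines. With only the arrays of the groups compared, which leaves fewer residual degrees of freedom, 514 genes passed limma at bladder E15, 291 at E18 and 0 in large intestine, where 665 had an unadjusted p under 0.05 with all arrays. The replicate block gave 19 genes in large intestine. Paired by number, knockout and wild type correlated at a median of −0.003 over 7 tissues and stages, so the numbers do not pair them.

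Of the added alternatives, leaving out the E19 arrays gave 1238 genes in the bladder mean and 1221 in the mean of 7, and leaving out the E15 arrays 2097 and 1742. The actin covariate gave 3 at bladder E15, 2059 in proximal stomach and 1185 in the bladder mean. Covariates for Xist and Eif2s3y gave 1 in distal stomach, 1 in small intestine and 38 in large intestine.

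Leaving out 1 array at a time gave these lowest and highest counts, each with 1 array in a group. Bladder E15 ranged from 126 to 1783, E18 from 164 to 311, E19 from 1364 to 1990 and the bladder mean from 1840 to 3511. Distal stomach ranged from 0 to 252, small intestine from 0 to 14, large intestine from 4 to 121, and proximal stomach from 3003 to 4022. E18 against E15 ranged from 37 to 317 and E19 against E18 from 315 to 687. The mean of the proximal stomach signature in bladder ranged from −0.16 to −0.061, and that of the distal stomach signature in proximal stomach from 0.44 to 0.70. The lists passing camera numbered 39 to 57. The endothelial list in large intestine ranged from −0.76 to 0.034, reversed without knockout replicate 2, and the Hedgehog list in distal stomach from 0.0019 to 0.37, with the lowest, of opposite direction by camera, without wild-type replicate 1. Signals near the arrays' floor, such as those of cornified genes in the knockout, limit how large a change can be measured in either direction.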

Other observations

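The tests of explanations for the large intestine and sex-linked patterns were chosen after these results were seen, and the splits of the arrays were planned.

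Markers of nerve and immune cells were higher in the mean of the knockout bladders. Neuron and glia genes rose in 14 of 21 cases with 1 lower, 16 and 1 adjusted over the list alone, among them Prph (1.88, SE 0.31, adjusted p = 2.7e-04) and Tubb3 (1.55, SE 0.31, adjusted p = 0.0017). Immune genes rose in 9 of 16 cases, 10 adjusted over the list alone, with Coro1a at 0.57 (SE 0.10) and Cd52 at 0.78 (SE 0.18). Without the 4 E19 arrays Coro1a rose by 0.25 (adjusted p = 0.229) and Cd52 by 0.67 (adjusted p = 0.076). Skeletal muscle genes rose in 7 of 16 cases, 12 adjusted over the list alone, hypoxia and glycolysis genes in 7 of 13 with 1 lower, 8 and 1 adjusted over the list alone, enteroendocrine genes in 5 of 15, 6 adjusted over the list alone, and mesothelial genes in 5 of 10, 5 adjusted over the list alone. The knockout E15 arrays, which had the highest 3' minus 5' actin signal (1.33 and 1.12), also had the largest mean changes of the neuron (0.99) and skeletal muscle lists (1.16) of the 3 stages.

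Wild-type stomach regions also differed in smooth muscle and enteroendocrine genes. Smooth muscle genes were higher in proximal than distal stomach in 13 of 20 cases with 1 lower, 14 and 1 adjusted over the list alone, and enteroendocrine genes lower in 11 of 15 with 1 higher, 11 and 1 adjusted over the list alone.

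The grouping by genotype was set against other splits of the arrays within each stage or tissue. For the bladder mean 1 of 100 splits drawn from 108 gave as many genes, the real one with 2857. The highest other gave 1301 and kept the real groups at 2 of 3 stages. The real split thus gave the most genes of those drawn, which chance would rarely give. The other splits mix the genotypes, so a genotype difference enters their spread and lowers their counts. RNA quality at E15 and fetal sex at E19 go with genotype, and the splits cannot tell these apart from it. For the mean of all 7 tissues and stages 2 of 100 did, the real one with 1870 and another with 2173. The other kept the real groups in 5 of the 7, proximal stomach included. Splits with the real groups in proximal stomach gave 295 to 2173 genes and those without 0 to 29, so the count followed that tissue. The splits regrouped each tissue on its own, although the replicate numbers pair gut arrays, so for this mean chance is not excluded.

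In knockout large intestine 8 genes of cornified cells rose. Tissue of the knockout proximal stomach cannot be their source, since 5 of the 8 were lower in both knockout proximal stomach arrays than in both knockout large intestine arrays. An implied share of 2.43% wild-type proximal stomach RNA would raise 150 genes of its signature by 1 or more on the log2 scale. Of these 86.7% stayed below the midpoint of that rise. That share too rests on genes picked for rising, so a smaller one is not excluded. Surface epithelium next to the gut stays open: the mean change of Krt5, Krt14, Krt1 and Krt10 was −0.39, but no array holds that epithelium from a knockout. A change within the gut of knockout embryos, as the genotype allows, was not tested and may also account for the pattern.

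In the 4 knockout gut tissues replicate 2 expressed neither Xist (4.40 to 4.90) nor the Y-linked gene Eif2s3y (4.06 to 4.19), while replicate 1 expressed Eif2s3y. In wild-type gut replicate 1 expressed Eif2s3y and replicate 2 Xist. A candidate explanation is a fetus with a single X chromosome. Genes that escape X inactivation, namely Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Pbdc1, would then not be higher in replicate 2. Their mean difference between replicate 2 and 1 was −0.0082 over the 4 knockout tissues and 0.364 over the 4 wild-type tissues, which is consistent with it. Loss of a Y chromosome from male tissue would give the same values and stays open.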
